A study of Arabidopsis thaliana with 4 samples.

How the data were processed

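Gene expression was measured in the above-ground parts (leaves, or whole plants without roots, per the labels) of Arabidopsis thaliana (Columbia-0) plants on 4 two-colour spotted cDNA arrays, 1 for each of the feeding times 2, 5, 10 and 24 h. Per the labels, soil-grown plants 21 days old were each exposed to 25 adult females of the western flower thrips, a sap- and cell-feeding insect, that had been starved for 3 h. cDNA of the fed plants carried the red dye Cy5 and cDNA of untreated plants the green dye Cy3 on every array, and no dye swap was made. Per the labels, each sample held 30 to 70 plants, 3 to 4 experiments were pooled before RNA extraction, and 2 to 3 arrays were run with the same RNA. The 4 arrays used here are 1 per time, and any further array is not used here.

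Per the labels and the series' design text, polyA RNA was labelled, the slides were scanned on a ScanArray Lite and quantified with ScanArray Express software, and the spot value is the median over pixels. The deposited scanner files give foreground and local background intensity per spot and dye on a linear scale, and these intensities were the starting point. Per the file headers, channel 1 is Cy3, channel 2 is Cy5, laser power was 90 for both dyes, and the detector gain was 69 for Cy3 on all arrays and 58, 65, 60 and 60 for Cy5 at 2, 5, 10 and 24 h. Per the file headers, the scanner software also scaled to the total signal, a step that the intensities used here do not include. The deposited files also give the percent of saturated pixels per spot; the median Cy5 foreground reached the scanner's ceiling in 2, 4, 0 and 1 spots at 2, 5, 10 and 24 h and in 0 spots in Cy3, and such spots were kept.

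A deposited value table of the whole series holds 1 natural log value per clone and array. Its scale, centring and direction are not given in the sources used here. Set against the log of the scanner's Cy5 over Cy3 ratios across clones, its columns had slopes of 1.01, 1.00, 1.02 and 0.996 and correlations of 0.996, 0.995, 0.993 and 0.994, so its values were read as the natural log of Cy5 over Cy3. Its lambda DNA row is at 0 on every array to within rounding. The column medians were 0.301, 1.20, 0.606 and 0.861 in natural log units. At 10 h, 8 values sat at the log of 0.01 and were left out as a floor. This table served only as an alternative.

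Each array carried 2560 spots in 12 print blocks. Of these, 2366 spots belonged to 1182 cDNA clones, and the rest were DNA of bacteriophage lambda (80 spots), alpha tubulin (54), negative control (26), GFP (6) and 28 spots whose names are bare numbers. The scanner's flag value 3 was read as a good spot because spots with the other values were dimmer in both dyes; other flags and control spots were left out of tests. Good clone spots numbered 1388, 1653, 1428 and 1393 at 2, 5, 10 and 24 h. A clone was tested when its foreground median exceeded the background median by 2 background SD in at least 50% of its spots, in at least 1 channel, on at least 2 arrays. With 1 array per time, the number of arrays limits the precision.

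Gene names came from the platform's table of gene names, updated through gene identifiers to the TAIR10.1 annotation, which was used for names only. Of the 1196 probes of the value table, 416 have 1 gene symbol, 0 have several and 780 are unnamed here; 415 of the 416 matched by identifier. One named probe is the alpha tubulin control, so 415 of the 1182 clones are named. The named genes can be old names of the array's design. Unnamed clones enter all counts. The build behind the array's clones is not given in the sources used here, so no coordinates are printed. The probes are long cDNA clones, and close relatives such as KIN1 and KIN2, COR15A and COR15B, BGLU21 and BGLU22, or JAL33 and JAL34 may share signal.

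Computations used R 4.3.3 and limma 3.58.1. Background was corrected with normexp at an offset of 50, log2 ratios of Cy5 over Cy3 were normalized by loess within each array with control and unusable spots at weight 0, and the spots of a clone were averaged. Loess sets the middle of the clones near 0, so every change is relative to the median clone of an array selected for stress-related genes. The change over the time course is the limma intercept over the 4 arrays with eBayes and Benjamini-Hochberg adjustment, at a threshold of 0.05. The SE given after ± is the moderated one, in which eBayes draws each clone's variance toward a common value. It can be larger or smaller than the SE from the clone's own arrays. The trend is the slope on log2 of hours for clones with values on at least 3 arrays. No time point can be tested alone: at each time, clones were counted when the log2 ratio was at least 1 in size, all usable spots had the same direction, and the brighter channel was above background. The SD over the spots of a clone is technical. With loess, the adjusted p-values rest on the spread between the 4 time-point arrays, moderated over clones. Whether these arrays shared 1 untreated RNA pool is not given in the sources used here. If they did, the spread of the untreated plants is left out. Relative to lambda DNA and in the deposited value table, moderation in effect gave all clones a common spread. Adjusted p-values there follow a gene's mean and its number of arrays, not its own spread. A gene's own dye effect cannot be separated from feeding. Where the dimmer channel was not above background, the fold at that time is given as a lower bound, from per-channel values after loess and Aquantile normalization and open to dye effects. For it, the dim channel was raised to the lowest value of any clone above background. Where the dim channel's own value was already above that lowest value, no bound was set and the measured ratio is given. Means over arrays and ranks use the measured ratios, those with a dim channel included, and such a mean is no bound.

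The 16 gene lists were fixed before the data were examined, and camera with a preset correlation of 0.01 was planned for lists with at least 4 measured members. Clones missing on an array would drop out of camera, so its statistic was computed from the moderated values of the limma fit over all tested clones (cameraPR). This form was chosen after camera on complete clones had been run and its p-values seen. On complete clones, the ABA list of the report had camera adjusted p = 0.462, and the jasmonate and PYK10 lists of the closing part had camera adjusted p = 0.0300. One fixed list reached 4 members. The 9 further lists were drawn up after the gene names on the array were known and before any value per gene had been seen; they were adjusted as a separate family. At each time, the percentile of a list's median among 10000 random lists matched on brightness in 10 bins is given as a description.

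The rule for named genes was fixed before the data were examined. It takes the 12 highest and 12 lowest means among genes past the threshold with 1 direction on all 4 arrays, the 5 highest and 5 lowest at each time among the counted genes, the 5 steepest trends each way past the threshold, the 3 largest members of each fixed list with at least 4 measured members, and a set of hormone reporters. Ranks were taken among named clones. Other list members are named only to describe their list.

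The tests were checked on simulated values for the tested clones with 200 changed clones. Over 806 clones, the mean test recovered 14.9% of changes of 0.5 log2, 83.6% of changes of 1 and 97.0% of changes of 2, with 4 false calls among 134. Over 716 clones, the trend test recovered 47.0% of slopes of 0.5 and 95.0% of slopes of 1, with 9 false calls among 151. The simulated noise was independent and Gaussian, with each clone's moderated variance, and planted slopes were exactly linear on log2 hours. These shares hold for such values only and are no measure of power in the real values. There, a slope of -1.33 for AT4G36850 did not pass (limma adjusted p = 0.202). Alternatives covered background correction, normalization, pixel summary, filters, spot flags, the deposited table, each array left out, statistical models and thresholds. Scaling on the 28 spots named plainly lambda DNA or on the alpha tubulin spots, the slide as a block and each slide alone were added after seeing the data. Per the file headers, the 2 h and 5 h arrays were on 1 slide and the 10 h and 24 h arrays on another.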

Results

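The time course followed transcripts in the above-ground parts of Arabidopsis plants after 2, 5, 10 and 24 h of feeding by western flower thrips, each time against untreated plants grown alongside. The array carried 1182 clones chosen for a link to stress. A usable ratio was obtained for 718, 857, 739 and 718 clones at 2, 5, 10 and 24 h. Over the usable clone spots, the median foreground intensity was 1097, 1150, 895 and 956 in Cy3 (untreated), above median backgrounds of 105, 106, 127 and 125. In Cy5 (fed) it was 1372, 2063, 1536 and 1325, above backgrounds of 178, 234, 331 and 207. The median SD between the spots of a clone was 0.10, 0.11, 0.12 and 0.11 log2. The SD of log2 ratios over clones was 1.11, 1.29, 1.60 and 1.28, widest at 10 h. None of the GFP or negative control spots was usable on any array. There were no replicate arrays within a time.

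The zero point sets which clones appear lower. With loess, the median tested clone lay at -0.11, -0.04, -0.07 and -0.02 log2 at 2, 5, 10 and 24 h. Relative to the lambda DNA spots, it lay between 0.70 at 2 h and 1.79 at 5 h. Relative to the alpha tubulin spots, it lay at 0.84, 1.31, 0.94 and 1.71. All values below are relative to the median clone, and a lower value means lower than that clone.

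**Figure D1:**
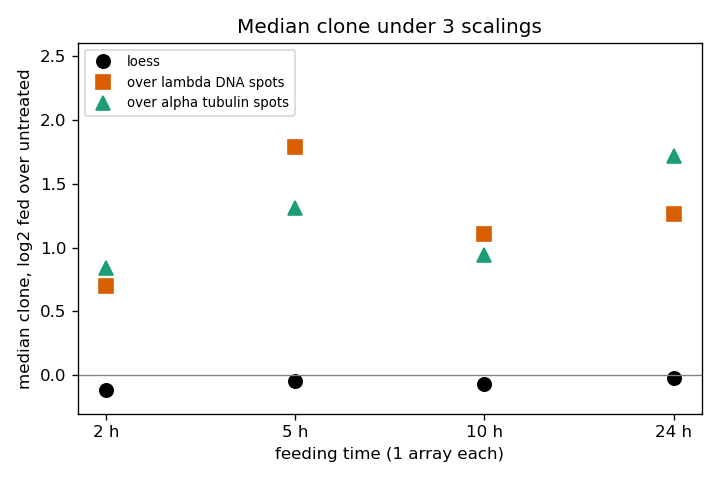
Median log2 ratio of fed over untreated plants among tested clones (y axis) on the array of each feeding time (x axis), with loess, relative to lambda DNA spots and relative to alpha tubulin spots. The loess medians lie near 0, while the medians over both controls lie above 0 on all 4 arrays, from 0.70 at 2 h to 1.79 at 5 h.

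The first comparison asked which genes differed between fed and untreated plants across the whole time course. The gene with the highest mean was AT5G05600, which encodes a jasmonate-hydroxylating oxygenase, at 4.46 ± 0.24 log2 (moderated SE, 4 arrays, limma adjusted p = 8.47e-05), a 22.0-fold higher level in fed plants. AT3G28220, which encodes a protein with TRAF-like domains, rose by 4.40 ± 0.30 (limma adjusted p = 0.000137). FAMT, a farnesoic acid methyltransferase, rose by 3.66 ± 0.30, and the jacalin-type lectin gene AT1G52000 by 3.66 ± 0.21. The GDSL lipase-like gene AT1G54010 rose by 3.17 ± 0.38, the lectin JAL34 by 2.57 ± 0.30 and NAI2, needed to form ER bodies, by 1.94 ± 0.24. The peroxidase gene AT5G64120 rose by 2.42 ± 0.19 and the leucine-rich repeat gene AT2G34930 by 2.39 ± 0.33. AT3G28270 and AT5G54170 rose by 2.09 ± 0.24 and 1.86 ± 0.18, and the cold- and ABA-inducible KIN2 by 1.86 ± 0.44 (limma adjusted p = 0.0132). Each of these 12 genes was higher on 4 of 4 arrays. KIN2 did not pass without the 5 h array (limma adjusted p = 0.0536) or on the 10 h and 24 h slide alone (limma adjusted p = 0.120). At 24 h it stood at only 0.48 log2, with an SD between spots of 0.49.

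Among the lowest means, DRT100, a leucine-rich repeat protein named for DNA-damage tolerance, fell by 2.94 ± 0.35 log2 (limma adjusted p = 0.000997). It was at least 5.44-fold and 7.16-fold lower at 2 and 10 h, and 5.95-fold lower by measured ratio at 24 h. Fed plants were not above background for DRT100 at these 3 times. The glutaredoxin-family gene AT1G64500 fell by 2.77 ± 0.58, the aspartyl protease gene AT3G54400 by 2.70 ± 0.21 and the GDSL lipase gene AT1G29660 by 2.61 ± 0.49. For AT3G54400, fed plants were not above background at 5, 10 and 24 h, where it was at least 4.41-fold, 5.63-fold and 4.05-fold lower. The lipid-transfer-type gene AT2G45180 fell by 2.05 ± 0.33, the pectin methylesterase gene AT3G49220 by 1.97 ± 0.26, AT3G16670 by 1.88 ± 0.20 and FUG1, a chloroplast translation initiation factor, by 1.79 ± 0.25. The acid phosphatase gene AT5G44020, AT1G73110, the subtilase gene AT2G05920 and the leucine-rich repeat gene AT3G20820 fell by 1.76 ± 0.37, 1.73 ± 0.27, 1.70 ± 0.19 and 1.59 ± 0.23. Each was lower on 4 of 4 arrays. On the 2 h and 5 h slide alone, AT5G44020 did not pass (-0.94, limma adjusted p = 0.0605). Relative to lambda DNA, all 12 stayed below 0, but AT3G49220, AT3G16670, FUG1, AT5G44020, AT1G73110, AT2G05920 and AT3G20820 no longer passed the threshold; relative to alpha tubulin AT2G45180 did not either. In the deposited value table, AT1G64500, AT1G29660, FUG1, AT5G44020, AT1G73110 and AT2G05920 did not pass (limma adjusted p from 0.0550 for AT1G73110 to 0.154 for FUG1).

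**Figure D2:**
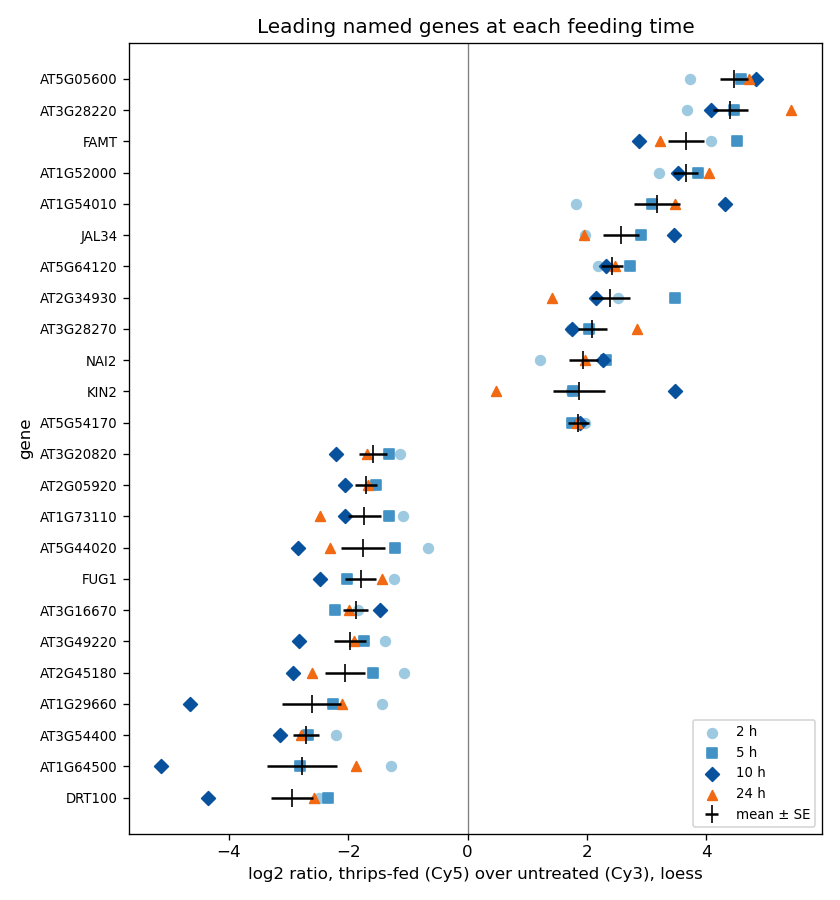
Log2 ratio of fed over untreated plants (x axis) for the 12 highest and 12 lowest named genes (y axis), with 1 marker per feeding time at the measured ratio, also where a dye was not above background, and the mean over 4 arrays ± moderated SE as a black bar. AT5G05600 has the highest mean, 4.46, and DRT100 the lowest, -2.94; relative to lambda DNA the 12 low genes stay below 0, 7 of them no longer past the threshold.

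In all, 379 of 806 tested clones passed the threshold, 182 higher and 197 lower in fed plants, and 436 had an unadjusted p under 0.05. Named genes made up 107 of the 379, with 52 higher and 55 lower. Scaled on lambda DNA, 543 were higher and 21 lower; scaled on alpha tubulin, 538 and 17; in the deposited value table, 454 and 31. Control scaling changes the zero point and also leaves out the loess correction for brightness. Median centring leaves out that correction too but keeps the middle of the clones near 0, and it gave 216 higher and 196 lower. Control scaling differs from median centring only in the zero point of each array, so most of the move came with the zero point. All 182 higher clones were called higher under both control scalings. Both scalings raised the median clone on every array, so this was close to fixed in advance and is no check on these calls. Relative to lambda DNA, 114 of the 197 lower clones had a value above 0. With the slide as a block, 383 of 716 clones passed; the 2 h and 5 h arrays alone gave 206 and the 10 h and 24 h arrays alone 161. Without the 5 h array the count was 222 of 728, and without eBayes moderation it was 172.

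The second comparison described each time point, with no test because each time has 1 array. By measured ratio, AT5G05600, AT3G28220 and AT1G52000 were among the 5 highest named genes at every time, and DRT100 and AT3G54400 among the 5 lowest. AT5G05600 stood at 3.72, 4.58, 4.83 and 4.71 log2 at 2, 5, 10 and 24 h, with SDs between spots of 0.08, 0.27, 0.01 and 0.07. FAMT stood at 4.51 at 5 h and was at least 5.80-fold higher at 10 h, where untreated plants were not above background. AT3G28220 stood at 5.41 at 24 h and AT1G54010 at 4.31 at 10 h. AT3G15450 entered the 5 highest at 2 h (2.65), AT2G34930 at 5 h (3.47) and KIN2 at 10 h, where it was at least 9.31-fold higher.

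Among the lowest genes, AT1G07440, a tropinone reductase-like gene, AT2G25510 and ECS1 were listed at 2 h, at -2.14, -2.08 and -1.99. The means of ECS1 and AT2G25510, -1.14 and -1.20, were 0.05 and -0.03 relative to lambda DNA. AT1G64500 and AT1G29660 were at least 18.5-fold and 15.2-fold lower at 10 h, and AT1G66180 was 7.88-fold lower by measured ratio. Fed plants were not above background for any of these genes at 10 h. AT2G45180 and AT1G73110 were listed at 24 h, at -2.61 and, as a bound, at least 4.18-fold lower. AT4G36850 was at 1.48 at 2 h and -0.65 at 5 h. It was 6.10-fold lower by measured ratio at 10 h, with fed plants not above background, and at least 5.52-fold lower at 24 h.

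At least 2-fold higher levels in fed plants were counted for 140, 163, 161 and 140 clones at 2, 5, 10 and 24 h, and lower levels for 90, 135, 165 and 115. Relative to lambda DNA the higher counts were 280, 678, 390 and 427 and the lower counts 10, 9, 49 and 11. Of 607 clones measured at all times, 70 were at least 2-fold higher at every time and 41 at least 2-fold lower. At 2 h and 5 h together, 100 clones were higher, against 26.2 for independent lists, and at 10 h and 24 h 87 clones, against 24.9. Across clones, the log2 ratios of different times correlated between r = 0.75 (2 h and 24 h) and r = 0.88 (5 h and 10 h). Clones are not independent replicates, and a dye effect or untreated RNA in common would raise these values too.

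The third comparison asked which genes changed steadily with feeding time. No clone passed the threshold for a slope on log2 hours among 716 tested with limma, and 67 had an unadjusted p under 0.05, where 35.8 are expected by chance. That excess over chance did not hold with the slide as a block (9 of 607) or without the 2 h array (19 of 649). Nor did it hold without the 5 h array (23 of 609), relative to lambda DNA (19 of 716) or in the deposited value table (21 of 716). It held without the 24 h array (145 of 655), without the 10 h array (74 of 624) and relative to alpha tubulin (59 of 716). The count of clones past the threshold depended on the last array: without 24 h, 56 of 655 clones passed, 23 rising and 33 falling from 2 to 10 h. Where a 24 h value existed, 17 of 21 rising clones were lower at 24 h than at 10 h, and 29 of 31 falling clones were higher. Picking clones on the arrays up to 10 h favours such turns. In that fit the 10 h array was the only one on its slide, so time and slide cannot be fully told apart. Scaled on alpha tubulin, 2 clones passed, and 1 clone passed in the deposited value table. The difference of late minus early arrays gave 0 clones, with 45 at an unadjusted p under 0.05, but it is also the difference between the 2 slides, and time and slide cannot be told apart in it. With the slide as a block, 0 of 607 clones had a trend.

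The fourth comparison concerned the gene lists. Of the fixed lists, the ABA, drought and cold list had 5 measured members, of which KIN2 and COR15A (1.82 ± 0.42 log2, 3 arrays, limma adjusted p = 0.0162) rose and 3 did not pass; adjusted over the list alone, 2 passed. Without the 5 h array, COR15A did not pass (limma adjusted p = 0.0513). It stood at 1.07 on 1 spot at 2 h, at 1.34 with an SD between spots of 0.84 at 5 h, and at 3.05 at 10 h. At 24 h it had no value. COR15B stood at 0.86 ± 0.37 and KIN1 at 0.50 ± 0.38 on 2 arrays each, and COR47 at -0.07 ± 0.23. Untreated plants were not above background for COR15B and KIN1 on any array, so their ratios rest on a dim channel. Relative to lambda DNA all 3 passed, with COR15B at 3.40 and KIN1 at 2.73 over that dim channel and COR47 at 1.14. The list as a whole did not pass (median 0.86, camera adjusted p = 0.134, and adjusted p = 0.624 with an estimated correlation, which used 2 members). Its median lay at the 98.3 percentile of matched random lists at 5 h and the 97.5 percentile at 10 h.

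The other fixed lists had at most 2 measured members, too few for a list test. The salicylate, glucosinolate, oxidative stress, heat shock, photosynthesis, circadian and housekeeping lists had 0 named members on the array, and the jasmonate signalling and senescence lists had 0 that could be tested. OPCL1, a jasmonate biosynthesis enzyme, rose by 1.81 ± 0.19 log2 on 4 of 4 arrays (limma adjusted p = 0.000649), and the lignin gene CCR2 by 1.24 ± 0.38 on 3 of 4 arrays (limma adjusted p = 0.0344). Each was the 1 tested member of its list, so adjustment over the list alone was no adjustment there. CCR2 rested on 1 spot at 2 h and at 10 h, with untreated plants not above background on 2 arrays. Adjusted over the list alone, 0 passed in the jasmonate- and wound-responsive, ethylene defence, early wound and root marker lists. PDF1.2, a defensin gene induced by jasmonate with ethylene, did not pass (0.64 ± 0.67, 3 arrays, limma adjusted p = 0.460); it stood at -0.31 at 5 h, -0.58 at 10 h and 2.82 at 24 h, and its mean without the 24 h array was -0.45. The thionin gene THI2.1 stood at 2.55 at 24 h and at -0.90, -0.02 and -0.54 before, with a mean that did not pass. EIN3, WRKY53 and STZ did not pass either, at -0.17 ± 0.18, 0.18 ± 0.24 and 0.81 ± 0.34. Relative to lambda DNA, EIN3 and WRKY53 stood at 1.04 and 1.67, THI2.1 at 1.47 and PDF1.2 at 1.98, all past the threshold. STZ passed relative to lambda DNA too, at 2.71, with untreated plants not above background at 2 h and 10 h. These passes do not weigh a gene's own spread, and THI2.1 and PDF1.2 were above 0 with loess at 24 h only. Relative to alpha tubulin, THI2.1 and PDF1.2 did not pass (limma adjusted p = 0.0603 and 0.0513). PYK10, listed as a root marker, stood at -0.27 at 2 h, 0.42 at 5 h and 2.86 at 24 h, and its mean did not pass (1.13 ± 0.48, limma adjusted p = 0.0930), though it passed relative to both controls. No other hormone reporter of the naming rule was measured under a gene name here.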

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

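The test on alpha tubulin below was chosen after the result was seen; the tests on brightness, dye effect and signs of arrays were set beforehand.

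AT4G36850 was at least 2-fold higher in fed plants at 2 h (1.48 log2) and at least 5.52-fold lower at 24 h, where fed plants were not above background and the measured ratio was -3.09 log2; the difference between 2 h and 24 h alone was not tested, and the trend over feeding time did not pass (slope -1.33 log2 per doubling of hours, limma adjusted p = 0.202). It was 1 of 5 clones with counted changes in both directions; the others, seen after their values were known, are AT2G37130 (-1.09 at 2 h, 1.14 at 24 h) and 3 clones without a gene name here. Of the 28 spots named with a bare number, which no comparison used, 6 were usable on each of the 4 arrays, while 0 of 26 negative control spots were.

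The median clone lay above the lambda DNA and the alpha tubulin spots on all 4 arrays. An unequal amount of lambda DNA in the dyes cannot be the whole account, since it leaves unexplained the part of the pattern seen over alpha tubulin, at least 0.84 log2 on every array (SE of the tubulin median 0.05 at 2 h). That value belongs to the pattern itself, and for the offset from the lambda DNA spots an unequal amount stays open. A dye effect that depends on brightness is argued against as the whole account of the lambda offset, since clones as bright as the lambda DNA spots had medians of at least 0.78 relative to these spots. Clones were not matched in brightness to the alpha tubulin spots, so such an effect on the tubulin offset was not tested. Together with a lambda difference, it stays open. Lower alpha tubulin transcript in fed plants together with a lambda difference also stays open, as does a rise of many stress-related clones on feeding, and no biological explanation was tested.

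Across the 4 arrays, 379 clones shared a log ratio away from 0. A fixed dye effect per clone may account for part or all of this and cannot be told apart from feeding, since fed plants were in Cy5 on every array. Called clones with a mean of at least 1 in size varied over times 1.16 times as much as clones that were not called (interval 1.03 to 1.34) after 1 factor per array. This value decides nothing, because a call itself needs a small spread over these arrays. Turning the signs of whole arrays gave at most 0 calls in the other 7 patterns, and 1 of 8 patterns, the real one, gave 379; with 8 patterns no share under 0.05 can be reached.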

How the results depend on the processing

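The control scalings, the slide settings and camera on complete clones were chosen after seeing the data. The count of changed clones stayed within 1.5 times of 379 under other background corrections, median centring, print-tip loess, mean pixels, the strict filter, low-quality spots kept, leaving out the 2 h, 10 h or 24 h array, an intensity trend and the slide block. Removing the filter changed no value. Scaling on the housekeeping list was not run, since it had 0 named members. No paired analysis was possible because each time has 1 array. The causes of the changes below were not tested, with 1 exception. Most of the move under control scaling came with the zero point. Counts with arrays left out or by slide rest on fewer arrays, but they also differed with the array left out, from 222 to 320. The deposited value table gave 454 higher and 31 lower clones and 1 trend, lambda DNA scaling 543 and 21, and alpha tubulin scaling 538 and 17 with 2 trends. At 2, 5, 10 and 24 h, the clones at least 2-fold higher numbered 245, 650, 341 and 417 in the deposited table, 280, 678, 390 and 427 on lambda DNA and 316, 539, 361 and 547 on alpha tubulin; those lower numbered 30, 13, 82 and 19, then 10, 9, 49 and 11, then 6, 16, 61 and 3. A 1.5-fold threshold gave 249 higher at 5 h and 208, 234 and 206 lower at 2, 5 and 24 h. The 2 h and 5 h slide alone gave 206 calls (116 higher, 90 lower), and the other slide 161 (92 and 69). Without moderation 172 passed (87 and 85). Leaving out 1 array gave 222 to 320 calls, with 120 to 162 higher and 102 to 161 lower, lowest without 5 h, and 0 to 56 trends, highest without 24 h and 1 without 10 h. The PDF1.2 mean ranged from -0.45 without 24 h to 1.26 without 10 h. Means of named genes lost the call in 25 comparisons and gained it in 6, and 432 stayed as they were. With fry, run only on members measured on all 4 arrays, the peroxidase, NBS-LRR and EF-hand lists gained the call (fry adjusted p = 0.0231, 0.0231 and 0.0416). List medians that changed sign, none past the camera threshold on either side, were EF-hand (0.11 with print-tip loess, 0.10 with low-quality spots, 0.92 in the deposited table, 1.07 on lambda DNA, 1.06 on alpha tubulin), NBS-LRR (0.73, 0.86 and 0.85 in the last 3 settings), amino acid catabolism (-0.032 with mean pixels), and, with low-quality spots, peroxidases (-0.078) and UDP-glycosyltransferases (-0.013). Signal over background limits some ratios: the dimmer channel of 27, 59, 105 and 46 clones was not above background at 2, 5, 10 and 24 h. For 25, 46, 72 and 39 of these clones it was the untreated channel.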

Other observations

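The lists in this part were drawn up after the gene names on the array were known, before values were seen. The list of genes tied to jasmonate passed as higher in fed plants in the main setting, but not in all others. Of 6 measured, AT5G05600, FAMT and OPCL1 rose and 3 did not pass (median 1.54 log2, camera adjusted p = 0.0364, but camera adjusted p = 0.502 with an estimated correlation). THI2.1 was lower on 3 of 4 arrays and PDF1.2 on 2 of 3. Of the list's measured members, OPCL1, THI2.1 and PDF1.2 also belong to fixed lists. AT2G38240, a relative of AT5G05600, did not pass; untreated plants were not above background on any array, and the lower bound was 1.72-fold at 2 h, 4.29-fold at 5 h, with no fold to give at 10 h and 24 h. The PYK10 complex and ER body list, a beta-glucosidase system with its lectins and lipase-like partners, had 7 measured members, of which AT1G54010, JAL34, NAI2 and BGLU21 (0.75 ± 0.24) rose and PYK10, BGLU22 and JAL33 did not pass (median 1.13, camera adjusted p = 0.0364, but adjusted p = 0.677 with an estimated correlation). Those 3 passed relative to both controls, at 2.46, 2.09 and 2.31 relative to alpha tubulin, where JAL33 turned from -0.17. Control scaling leaves out the loess correction for brightness too. Median centring, which leaves it out but keeps the middle near 0, put the list median at 1.51, against 2.84 on alpha tubulin. JAL33 was measured at 10 h and 24 h only, where the median clone lay at 0.94 and 1.71 relative to alpha tubulin. Its turn was larger than that zero point gives, so part of it came with leaving out loess. The parts were not separated for each gene. For BGLU21, untreated plants were not above background on its 3 arrays. It was 1.52-fold higher by measured ratio at 5 h and at least 1.75-fold and 1.22-fold higher at 10 and 24 h. The list's median lay at the 96.3, 99.0, 99.2 and 100.0 percentile of matched random lists at 2, 5, 10 and 24 h. Both lists lost the call with print-tip loess (adjusted p = 0.0536), without the 24 h array (adjusted p = 0.101 for the jasmonate list and 0.0709 for the PYK10 list) and with alpha tubulin scaling (adjusted p = 0.129). With the slide as a block, chosen after seeing the data, both had adjusted p = 0.00938. On the 2 h and 5 h slide alone the adjusted p was 0.0439 for the jasmonate list and 0.166 for the PYK10 list, and on the other slide 0.0131 and 0.00719.

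Of 8 measured class III peroxidases, AT5G64120, Prx37 (1.62 ± 0.43, 2 arrays) and AT4G37520 (0.93 ± 0.24) rose. AT1G44970 and AT5G40150 (2 arrays) fell by 0.81 ± 0.22 and 1.52 ± 0.38, though both stood above 0 relative to lambda DNA (0.50 and 0.27). At 24 h, AT5G40150 rested on 1 spot with fed plants not above background, and was at least 3.68-fold lower. The list did not pass (camera adjusted p = 0.817). Of 8 measured genes for NBS-LRR resistance proteins, AT1G61180 and AT4G19500 fell by 1.15 ± 0.19 and 0.87 ± 0.20 and 0 rose (camera adjusted p = 0.184), but relative to lambda DNA both stood above 0 (0.05 and 0.29) and the list median of -0.45 turned to 0.86. The berberine bridge enzyme-like genes AT4G20830 and AT4G20840 rose by 1.58 ± 0.22 and 1.84 ± 0.19, and AT1G26380 did not pass (1.08 ± 0.39); 3 members were too few for a list test. ALDH7B4 rose by 1.51 ± 0.27 in the wider ABA and dehydration list, of which KIN2 and COR15A rose too and 4 of 7 did not pass (camera adjusted p = 0.184). Of 5 UDP-glycosyltransferases, UGT72E1 fell by 0.64 ± 0.20 (0.61 relative to lambda DNA) and 4 did not pass (camera adjusted p = 0.937). Of 4 EF-hand genes, AT4G27280 rose 2.03-fold in the mean of 3 arrays, with untreated plants not above background at 10 h, AT2G41090 fell by 1.51 ± 0.24 (-0.056 relative to lambda DNA, where it did not pass) and 2 did not pass (camera adjusted p = 0.817). Of 4 amino acid catabolism genes, MCCB fell by 1.09 ± 0.31 on 2 arrays (0.27 relative to lambda DNA) and 3 did not pass (camera adjusted p = 0.937). The UDP-glycosyltransferase and amino acid catabolism lists had medians of 0.090 and 0.098 but means of -0.0042 and -0.059 and a test direction below 0. Calls of members are relative to the median clone: of the 32 members of all lists that did not pass, 29 passed as higher relative to lambda DNA and 28 relative to alpha tubulin. With fry, which asks whether a list's own genes move one way on balance and does not compare them with other genes, the peroxidase, NBS-LRR and EF-hand lists passed (fry adjusted p = 0.0231, 0.0231 and 0.0416). It used only members measured on all 4 arrays: 4 of 8 peroxidases, 6 of 8 NBS-LRR genes and 3 of 4 EF-hand genes. The EF-hand gene that rose, AT4G27280, was left out.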
